A study of Bos taurus with 29 samples.

How the data were processed

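Skin biopsies of Holstein-Friesian cattle were profiled by 3′ end RNA sequencing of messenger RNA ends, with 1 library per sample and 29 libraries in 6 groups: M0 (control skin, 5), M1 (5), M2 (5), M3 (5), M4 (5) and M4.1 (4). Groups were taken from the sample labels. Per the labels, 22 lesion samples came from 6 farms, and the 5 M0 samples and 2 of the M1 samples came from a slaughterhouse. No label gives the farm, animal or day of a sample, so no covariate was used.

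Per the submitters' processing notes, the authors used FastQC 0.11.7, cutadapt 2.8, STAR, RSEM 1.3.1 and edgeR with genome build ARS-UCD1.2. The notes give no version for STAR or edgeR. The deposited tables are 5, each setting 1 stage against the same M0 libraries. Per the file headers and the values, each holds whole-number counts per gene and library, and it is not stated whether RSEM values were rounded to make the counts. The authors deposited a normalized signal beside the counts, in CPM, which scales counts to a common library size, here the library total multiplied by the TMM (trimmed mean of M-values) factor within that table. The deposited group columns are means of this signal over the libraries of a group. The deposited p-values were recomputed from the counts as robust edgeR quasi-likelihood p-values on the 2 groups of each table, adjusted over that table by the method of Benjamini and Hochberg. The recomputed signal differed from the deposited signal by a relative 4.96e-15 at most. Each table lists only genes over 1 CPM in at least as many libraries as its smaller group holds.

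The tables list 11055, 11047, 10956, 10833 and 11303 genes for M1, M2, M3, M4 and M4.1, and 11479 genes in all. The 10629 genes listed in every table were joined, with the M0 columns used once. TMM factors were computed and genes filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left out 258 genes and kept 10371, and 534 genes of the fit have no symbol. All 29 libraries were fitted in 1 quasi-likelihood model with 1 coefficient per group. The stages were each tested against M0, and M2 against M1, M3 against M2, M4 against M3, M4.1 against M4 and M4 against M2. A gene is called, and described as risen or fallen, at an adjusted p under 0.05. Fold changes are on the log2 scale. Their standard errors (±) are approximate, taken as the absolute fold change over the square root of the F value of the test. Levels in CPM are means ± SD. The 850 genes in some tables only were tested within their own tables by the robust quasi-likelihood fit of edgeR.

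The 25 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1. A preset correlation of 0.01 between genes was used and the test repeated with an estimated correlation and with the rotation test fry. Members past the threshold were counted over all genes tested and with adjustment over the list alone. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15, from log2 CPM with a prior count of 2 for principal components and list scores.

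Genes were named by a rule fixed before the data were examined. In comparisons with M0 these are the cytokines of the IL-17 list, the 8 largest rises and 8 largest falls among called genes with a symbol and a mean above the median of the tested genes, and up to 3 members of each list with the smallest p. Between stages the rule takes 5 rises, 5 falls, IL17F and up to 2 members per list. Genes named outside the rule are said to be chosen after their values were seen. For a gene without counts in a group, a lower bound was computed with 3 counts over that group, and for 1 to 3 counts a ratio with a 95% counting interval is given.

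Libraries held 2858186 to 5399615 counts over the joined genes, so a gene with 3 counts lies near the floor. TMM factors ran from 0.631 to 1.29. The gene with the most counts took 6.68% to 19.5% of a library. The analysis was tested on simulated data drawn with the gene means, library totals and dispersions of the 29 libraries, with 200 genes changed in 1 group. With M1 changed and tested against M0, 54 of 97 genes with a true fold of 2 and 83 of 100 with a true fold of 4 were recovered, and 5 of 142 called genes were unchanged. With M2 changed and tested against M1, the numbers were 44 of 100, 88 of 99 and 10 of 142. The changed gene list was recovered in each, and 0 of the unchanged lists was called. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes.

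Alternatives fixed before the data were examined were RLE size factors, no filter, at least 10 counts in at least 10 libraries, the replicate number as a block, only the 2 groups compared, a test against a fold change of 1.5, limma-voom, the DESeq2 1.42.0 Wald test, the list test variants named above, and leaving out each replicate in turn. Chosen after the data were seen were the robust fit, the authors' layout of 1 table at a time, leaving out the 2 libraries with a TMM factor under 0.8, and refits of genes within their own tables. Other splits of the libraries were counted by drawing 60 of the 126 possible splits per comparison with a fixed seed. Left out were IL17A, which no table lists, and any analysis by farm or animal.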

Results

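Digital dermatitis is an infectious skin disease of the bovine foot. Its stages run from control skin (M0) through early (M1), acute ulcerated (M2), healing (M3) and chronic (M4) lesions to chronic lesions with a renewed active area (M4.1). Gene expression was measured by 3′ end RNA sequencing in 29 skin biopsies of Holstein-Friesian cattle, a dairy breed. There were 5 libraries each of M0, M1, M2, M3 and M4 and 4 libraries of M4.1. Per the labels, 22 lesion samples came from 6 dairy farms, whereas the 5 M0 samples and 2 of the M1 samples were taken after slaughter. The labels do not say which M1 samples these were. The M0 samples are labelled as skin from above the cleft between the claws and the lesions as lesion skin, so disease and body site cannot be separated in any comparison with M0. Sample source can be set apart from disease only through the 2 unnamed M1 samples. The labels do not say that replicates are different animals, so the p-values measure spread between samples.

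The deposited tables together list 11479 genes, and the 10629 genes listed in all 5 tables were analysed jointly. Over these genes the libraries held 2858186 to 5399615 counts, with 4348452 to 5335624 in M0 (n = 5), 3377174 to 4742526 in M1 (n = 5), 3454319 to 5399615 in M2 (n = 5), 2858186 to 4277078 in M3 (n = 5), 3651132 to 5036318 in M4 (n = 5) and 3148592 to 5207174 in M4.1 (n = 4). A gene without counts in a group can have up to 3 counts there at 95% confidence, and intervals and floors given here cover counting error only. In a principal component analysis the first component held 40.0% of the variance. The M0 libraries lay between -104 and -93.6 on it and the 24 lesion libraries between -0.308 and 39.0. On the second component (16.7%) the M4 libraries lay between -61.4 and -4.10 and the M4.1 libraries between 1.25 and 37.1, without overlap, while M1, M2 and M3 overlapped both.

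**Figure D1:**
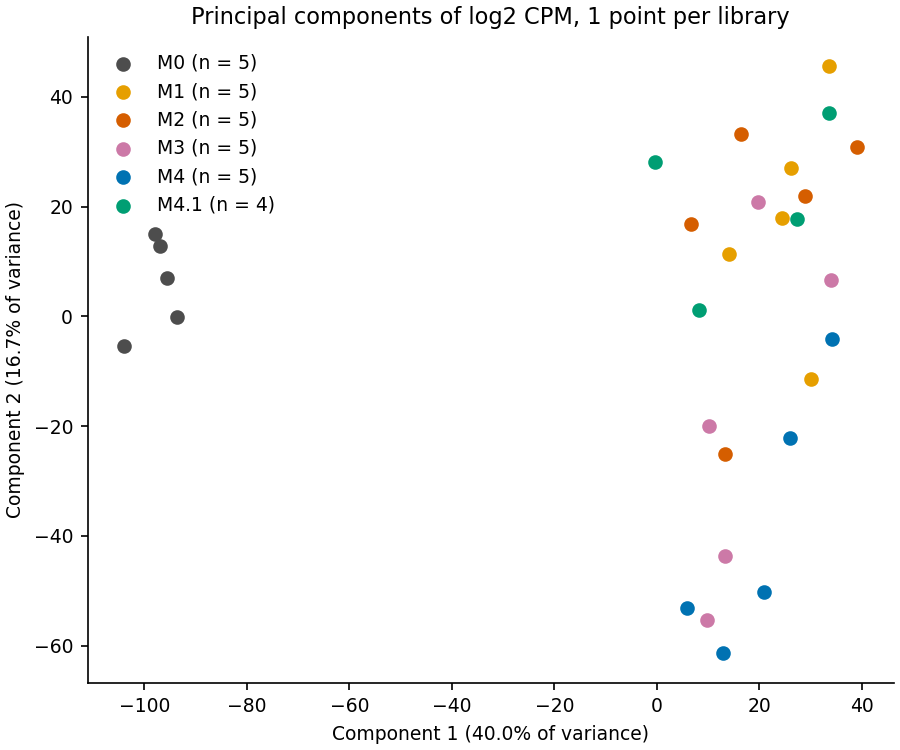
Principal components 1 and 2 of log2 CPM (axes in component units), 1 point per library, coloured by stage. M0 libraries lie between -104 and -93.6 on the first component and all 24 lesion libraries above them.

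Comparing M1 with M0 asks which genes differ in the early lesion. Single genes of neutrophil attraction and antimicrobial defence were among the largest rises. PI3 (ENSBTAG00000039028), which encodes the neutrophil elastase inhibitor elafin, rose from 0.501 ± 1.12 to 1087 ± 1061 CPM (counts scaled to a common library size, mean ± SD, n = 5 and 5). This is a log2 fold change of 11.03 ± 1.06 (SE, edgeR adjusted p = 3.9e-09), and all M0 counts of PI3 lie in M0 replicate 5. The chemokine CXCL8 (ENSBTAG00000019716), which recruits neutrophils, rose by 8.57 ± 1.28 on the log2 scale, and CCL11, which recruits eosinophils, by 9.03 ± 0.66. The beta-defensins TAP and LAP rose by 9.15 ± 1.37 and 7.88 ± 1.26, and reads can be shared between such close paralogs. KRT6B (ENSBTAG00000038033), a keratin of wounded epidermis, rose by 7.76 ± 0.63. Among genes with 1 to 3 counts in M0, the epidermal protease inhibitor A2ML1 had a ratio of 1818 (95% counting interval 622 to 8818) and the vitamin B12 carrier TCN1 a ratio of 646 (95% counting interval 178 to 5338). All rises and falls named for the comparisons with M0 are past adjusted p = 0.05.

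Genes of hair, sebaceous and sweat glands were among the largest falls in M1. The skin secretory protein genes BDA20 and MGC151921, which are similar in sequence, changed by -9.80 ± 0.81 and -9.63 ± 0.48, and the hair shaft gene KRTAP9-1 by -8.32 ± 1.16. PSAPL1, a prosaposin-like gene, changed by -7.88 ± 1.22. The apocrine secretoglobin SCGB1D was lower with an inverse ratio of 3259.7 (585 to 128779). The same inverse ratio was 1733 (311 to 68496) for the mucin-like gene MUCL1, 666 (228 to 3231) for the lipid transfer gene SEC14L6 and 418 (74.7 to 16541) for the serpin SERPINA12. Other antimicrobial genes fell, with S100A7 (psoriasin) at -6.81 ± 1.71, LCN2 at -3.23 ± 0.64 and LTF (lactoferrin) at -5.08 ± 0.67. In M1 against M0, 4459 of 10371 tested genes (43.0%) passed adjusted p = 0.05, 2274 higher and 2185 lower.

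**Figure D2:**
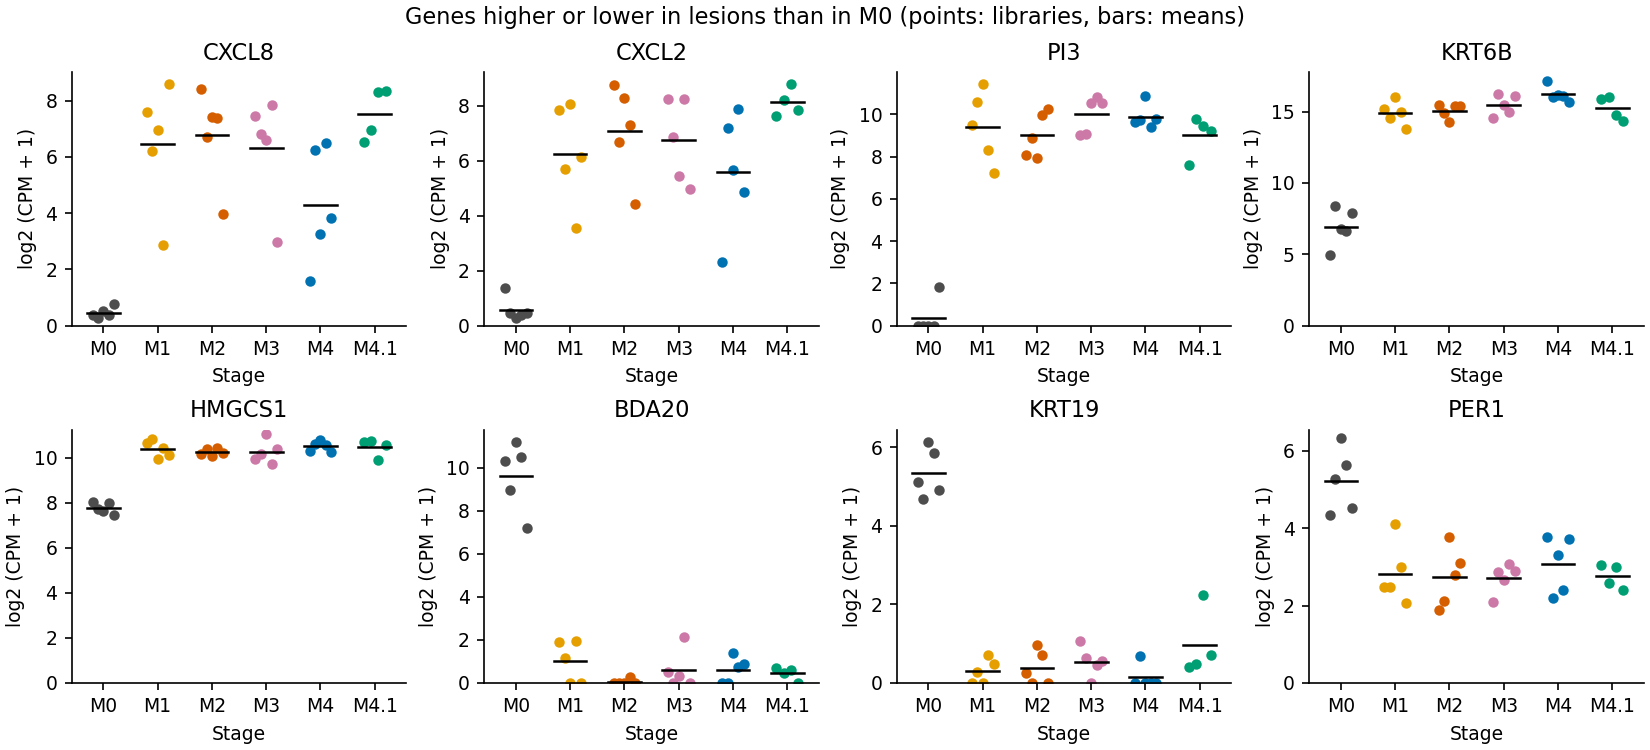
Level of 8 genes per library (y axis, log2 of CPM + 1) by stage (x axis), with 1 point per library and a bar at the mean. CXCL8, CXCL2, PI3, KRT6B and HMGCS1 are higher and BDA20, KRT19 and PER1 lower in the lesion stages than in M0, with a log2 change of 11.03 for PI3 in M1.

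M2, the acute ulcerated stage, was compared with M0 to ask which genes differ at the height of inflammation. The largest rises included single chemokine genes. CXCL2, GRO1 and CXCL8, whose products attract neutrophils, rose by 8.36 ± 1.2, 7.70 ± 1.09 and 8.58 ± 1.28 on the log2 scale, and reads can be shared between the first pair. PTGS2 (cyclooxygenase 2) rose from 2.75 ± 0.729 to 488 ± 262 CPM, a log2 change of 7.45 ± 0.98 (adjusted p = 7.7e-07). PI3 rose by 10.26 ± 1.04, CCL11 by 9.57 ± 0.67, TAP by 8.20 ± 1.33 and KRT6B by 7.83 ± 0.63, and A2ML1 had a ratio of 1293 (95% counting interval 442 to 6271). Matrix-degrading MMP9 and MMP12 rose by 6.72 ± 0.76 and 5.45 ± 0.75, and so did the fibrillar collagen genes COL3A1 (1.60 ± 0.41) and COL5A1 (1.54 ± 0.32).

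Glandular and hair genes were among the largest falls in M2 as well. BDA20 had an inverse ratio of 25940.4 (4655 to 1024620.0), MUCL1 of 1928 (346 to 76199.8) and SCGB1D of 1209 (413 to 5864). MGC151921 was at least 1374-fold lower. The secretoglobin SCGB2A2 changed by -7.76 ± 0.68, the hair genes KRTAP4-7 and KRT86 by -7.69 ± 1.01 and -7.45 ± 1.35, and the epithelial gene DAPL1 by -7.59 ± 0.80. In M2 against M0, 4374 of 10371 tested genes (42.2%) passed adjusted p = 0.05, 2253 higher and 2121 lower.

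M3, the healing stage, was compared with M0 to ask which changes are present while a lesion closes. Single epidermal defence and keratinocyte genes were among the largest rises. The beta-defensins TAP and LAP rose by 9.68 ± 1.39 and 9.29 ± 1.3, PI3 by 11.12 ± 1.06 and KRT6B by 8.28 ± 0.64 on the log2 scale. ARG1, an arginase of epidermis and myeloid cells, rose by 8.38 ± 1.45 (adjusted p = 4.2e-05). CCL11 rose by 8.40 ± 0.66. A2ML1 had a ratio of 2386 (95% counting interval 816 to 11575) and TCN1 a ratio of 569.7 (95% counting interval 157 to 4714). CASP14, a caspase of cornifying keratinocytes, rose by 3.66 ± 0.78. The chemokine CCL20, which attracts cells bearing CCR6, rose by 4.98 ± 1.01, and by 2.47 without M3 replicate 4.

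Hair and secretory genes were among the largest falls in M3. KRT31 was at least 1764-fold lower. KRTAP4-7 had an inverse ratio of 2938 (527 to 116073), FABP9 of 2572 (461 to 101593), SCGB1D of 1366 (378 to 11280.1) and MUCL1 of 1452 (260.4 to 57393). KRT86, KRTAP3-3 and BDA20 changed by -10.19 ± 1.64, -10.18 ± 1.41 and -10.59 ± 0.87. In M3 against M0, 4084 of 10371 tested genes (39.4%) passed adjusted p = 0.05, 2116 higher and 1968 lower.

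M4, the chronic stage, was compared with M0 to ask which changes persist in long-standing lesions. Single keratinocyte genes were among the largest rises. Of 25 cornified envelope genes, 10 rose over all genes tested and adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.65 with an estimated correlation). KRT6B rose from 159 ± 119 to 81928 ± 36780.4 CPM, a log2 change of 9.01 ± 0.66 (adjusted p = 3.3e-11). IVL (involucrin), which forms the cornified envelope, rose by 3.84 ± 0.45, CASP14 by 4.43 ± 0.81 and the desmosome gene DSG1 by 1.76 ± 0.30. ARG1 rose by 9.32 ± 1.49, TAP by 10.19 ± 1.41, LAP by 9.87 ± 1.32, PI3 by 10.92 ± 1.05 and CCL11 by 8.17 ± 0.65. A2ML1 had a ratio of 2382 (95% counting interval 814 to 11554) and TCN1 a ratio of 778 (95% counting interval 215 to 6435). The interferon-induced gene ISG15 rose by 5.40 ± 1.27 with all 5 libraries and by 2.57 (adjusted p = 0.057) without M4 replicate 3.

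Several hair and gland genes had few or no counts in M4. KRTAP4-7 was at least 952-fold lower, KRT35 at least 771-fold, SEC14L6 at least 542-fold and MUCL1 at least 471-fold. KRT31 had an inverse ratio of 2572 (712 to 21242). KRT25, a keratin of the inner root sheath, changed by -11.10 ± 1.88, the hair gene KRTAP1-1 by -10.90 ± 1.57 and ELOVL3, a fatty acid elongase of sebaceous glands, by -11.21 ± 1.87. In M4 against M0, 4396 of 10371 tested genes (42.4%) passed adjusted p = 0.05, 2207 higher and 2189 lower.

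M4.1, a chronic lesion with a renewed active area, was compared with M0 to ask which genes differ when disease flares again. Single chemokine genes were among the largest rises. CXCL8 rose from 0.387 ± 0.20 to 213 ± 123 CPM (n = 5 and 4), a log2 change of 9.01 ± 1.3 (edgeR adjusted p = 3.9e-06). CXCL2, GRO1 and PTGS2 rose by 8.89 ± 1.23, 8.30 ± 1.12 and 7.89 ± 1.0. PI3 rose by 10.15 ± 1.04, CCL11 by 9.35 ± 0.68 and KRT6B by 8.13 ± 0.64, and A2ML1 had a ratio of 1459.7 (95% counting interval 499 to 7082). MUCL1 was at least 522-fold lower. MGC151921 had an inverse ratio of 3349 (601 to 132321) and SCGB1D of 1473 (408 to 12168). BDA20 changed by -11.46 ± 1.0, SCGB2A2 by -7.10 ± 0.72, S100A7 by -6.23 ± 1.83, SERPINA12 by -5.70 ± 1.69 and the claudin CLDN8 by -5.59 ± 1.03. In M4.1 against M0, 4064 of 10371 tested genes (39.2%) passed adjusted p = 0.05, 2100 higher and 1964 lower.

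Gene lists fixed before the data were examined were tested in each comparison, and values here are in the order M1, M2, M3, M4 and M4.1, against M0. Of all 10371 genes, 2274, 2253, 2116, 2207 and 2100 rose and 2185, 2121, 1968, 2189 and 1964 fell. Counts of list members are to be read against these shares. They cover only members in the joint analysis, and symbols outside it were left out of all list tests. Most symbols of the T cell, B cell, dendritic cell, neutrophil and type 2 lists were left out in this way. The IL-17 list holds keratinocyte genes that IL-17 induces and the cytokines around it. Of 26 measured genes of the list, 18, 19, 18, 18 and 18 rose and 3, 3, 2, 2 and 3 fell over all genes tested. Adjusted over the list alone, 18, 19, 19, 20 and 20 rose and 3, 3, 2, 2 and 3 fell. Camera adjusted p was 8.5e-06, 5.2e-06, 1.5e-07, 3.9e-06 and 2.9e-07, and adjusted p was 0.18, 0.11, 0.079, 0.17 and 0.081 with an estimated correlation. Their median log2 fold change was 3.17, 2.75, 3.52, 2.97 and 3.02. LCN2 fell in every stage, and S100A7 fell in M1, M2 and M4.1. The call of S100A7 in M2 (-4.13) ended without any of M2 replicates 1 to 4 (-3.81 to -3.92, adjusted p = 0.053 to 0.062), and the value was -6.89 without M2 replicate 5. Wound and hyperproliferation genes mark regrowing epidermis. Of 21 measured genes of that kind, 16, 16, 15, 15 and 17 rose and 3 in each stage fell over all genes tested. Adjusted over the list alone, 17, 17, 16, 15 and 17 rose and 3 in each stage fell. Camera adjusted p was 3.0e-09, 3.4e-10, 3.5e-11, 5.6e-10 and 4.8e-12, and adjusted p was 0.033, 0.0073, 0.0040, 0.013 and 0.0036 with an estimated correlation. The fallers were simple-epithelium keratin genes, among them KRT8 and KRT19, which fell in all 5 stages. Of 30 cell cycle genes, 27, 26, 23, 22 and 25 rose and 0 in each stage fell over all genes tested. Adjusted over the list alone, 27, 27, 27, 24 and 26 rose and 0 in each stage fell. Camera adjusted p was 3.0e-09, 9.1e-08, 1.3e-05, 4.0e-04 and 2.1e-06, and adjusted p was 0.29, 0.40, 0.47, 0.59 and 0.46 with an estimated correlation. Without M4.1 replicate 4, 15 instead of 25 cell cycle genes rose in M4.1.

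Genes of hair follicles, sebaceous glands and sweat glands, which make hair, skin lipid and sweat, fell for the most part in all stages. Of 23 hair follicle and sebaceous gland genes, 0 in each stage rose and 21, 21, 20, 18 and 21 fell over all genes tested. Adjusted over the list alone, 0 in each stage rose and 21, 21, 20, 18 and 21 fell. Camera adjusted p was 7.9e-09, 4.3e-08, 1.7e-09, 6.2e-08 and 2.9e-06, and adjusted p was 0.18, 0.18, 0.16, 0.19 and 0.22 with an estimated correlation. Their median was -7.05, -5.97, -6.90, -7.43 and -3.89, or -6.78, -5.97, -5.72, -5.77 and -3.89 with genes lacking counts at their bounds. Of 11 sweat gland and simple-epithelium genes, 1 in each stage rose and 9, 8, 7, 7 and 8 fell over all genes tested. Adjusted over the list alone, 1 in each stage rose and 9, 8, 7, 7 and 8 fell. Camera adjusted p was 2.3e-04, 3.3e-04, 5.1e-04, 4.0e-04 and 6.5e-04, and adjusted p was 0.033, 0.038, 0.056, 0.067 and 0.038 with an estimated correlation. Outside the joint analysis, AQP5 of that list was called higher in M3 and M4, the only stages whose tables list it. CLDN10, by contrast, was called lower in every stage. Of 25 measured cornified envelope genes, which build the outer skin barrier, 6, 6, 8, 10 and 5 rose and 6, 1, 0, 0 and 3 fell over all genes tested. Adjusted over the list alone, 6, 5, 8, 10 and 5 rose and 8, 1, 0, 0 and 3 fell. Camera adjusted p was 0.77, 0.96, 0.040, 0.0034 and 0.88, and adjusted p was 0.96, 0.99, 0.74, 0.65 and 0.96 with an estimated correlation. Of 18 barrier lipid genes, 6, 5, 6, 8 and 5 rose and 6, 5, 3, 3 and 7 fell over all genes tested. With adjustment over the list alone, 6, 6, 6, 8 and 5 rose and 7, 7, 3, 3 and 7 fell. For them camera adjusted p was 0.81, 0.74, 0.12, 0.049 and 0.75, and adjusted p was 0.96, 0.94, 0.70, 0.55 and 0.93 with an estimated correlation. Without M2 replicate 5, 3 cornified envelope genes rose and 12 fell in M2, and 9 barrier lipid genes fell. Cornified envelope genes that rose in M4.1 numbered 3 without M0 replicates 1, 2 or 4 or M4.1 replicate 1, and 2 without M4.1 replicate 2, and 4 barrier lipid genes fell in M4.1 without M4.1 replicate 4. Without M2 replicate 3, 8 instead of 13 of the 25 lists passed the camera test in M2.

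Many genes changed in the same direction in every stage. CASP14 and LCN2 and, in single stages, ARNTL, KRT8, PER1, PTGS2 and S100A7 were named after their values were seen. HMGCS1, an enzyme of cholesterol synthesis, rose, with log2 changes of 2.66, 2.49, 2.57, 2.74 and 2.74 in M1, M2, M3, M4 and M4.1. FASN, which makes fatty acids, changed by -2.19, -1.74, -1.80, -1.76 and -1.87 in the same order. The fatty acid carrier FABP4 rose by 4.66, 4.75, 5.07, 5.53 and 4.84, while PPARG, the regulator of fat cell and sebocyte formation, changed by -4.58, -4.22, -4.07, -6.59 and -3.45. The gap junction gene GJB2 rose by 4.79, 4.82, 4.90, 4.86 and 4.71. In all 5 stages 1358 genes were higher and 1197 lower than in M0, where independent lists would share 4.34 and 3.39 genes. The stages share the 5 M0 libraries. Simulated unchanged stages had 0 such genes in either direction over 5 simulations. They were drawn around the observed M0 means, so they leave out the error of the shared controls and cannot show its effect. With M2 tested against M0 replicates 1 to 3 and M4 against replicates 4 and 5, 2093 genes were called in the same direction in both, compared with 3163 under shared controls. With replicates 1 and 2 against 3 to 5 there were 2167. These split fits also had fewer controls per test and no filter on low counts. The lower counts therefore cannot be put down to the sharing of controls alone. Across genes, which are not independent replicates, the fold changes of M2 and M4 had a Pearson r of 0.879 with shared controls. With split controls r was 0.828 and 0.848. The mean r of 0.0284 in simulated unchanged stages has the limit given above.

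Other lists are given as ranges over the 5 stages, and values after camera and estimated correlation are adjusted p. Of all 10371 genes, 2100 to 2274 rose and 1964 to 2189 fell. A count near these shares does not by itself set a list apart. Most clock genes fell, with the period gene PER1 at -2.56, -2.71, -2.88, -2.33 and -2.83. The core activator ARNTL changed by -1.68, -1.39, -1.72, -1.43 and -1.46. Of 10 clock genes, 6 to 7 fell and 1 to 2 rose over all genes tested and adjusted over the list alone, and the riser in every stage was BHLHE40 (camera 0.0051 to 0.11, estimated correlation 0.18 to 0.53). Smooth muscle myosin MYH11 changed by -1.88, -1.57, -2.06, -2.4 and -1.33, and of 9 muscle genes 4 to 7 fell over all genes and over the list alone (camera 0.0023 to 0.056, estimated correlation 0.19 to 0.46). GATA3, a factor of type 2 T cells and of epidermis, changed by -2.38, -2.43, -1.84, -1.42 and -2.26, and of 6 type 2 genes 3 to 4 fell over all genes and over the list alone (camera 0.030 to 0.049, estimated correlation 0.11 to 0.19). The glycolysis gene PGK1 rose by 1.67, 1.67, 1.44, 1.37 and 1.55, and of 19 hypoxia and glycolysis genes 9 to 10 rose and 1 to 3 fell over all genes, 9 to 11 and 1 to 3 adjusted over the list alone (camera 2.0e-04 to 0.0028, estimated correlation 0.16 to 0.22). S100A8, a calprotectin subunit of neutrophils and inflamed epidermis, rose by 3.81, 3.47, 4.24, 4.45 and 3.47, and of 8 neutrophil genes 4 to 5 rose and 2 fell over all genes, 4 to 5 and 2 to 3 adjusted over the list alone (camera 0.0095 to 0.043, estimated correlation 0.16 to 0.30). JUNB, an early response gene, rose by 1.61, 1.56, 1.42, 1.67 and 1.42, and of 19 immediate early and heat shock genes 5 to 7 rose and 0 to 1 fell over all genes and over the list alone (camera 0.015 to 0.046, estimated correlation 0.30 to 0.51).

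The remaining lists passed the camera test in at most 2 of the 5 stages. Their counts are likewise to be read against the shares of all genes that rose or fell. IL1A, an alarm cytokine of keratinocytes, rose by 3.76, 4.02, 3.92, 3.62 and 4.4, and of 19 IL-1 family genes 6 to 10 rose and 2 to 3 fell (6 to 11 and 2 to 3 adjusted over the list alone, camera 0.019 to 0.38, estimated correlation 0.47 to 0.86). The camera test of that list passed in M4.1 alone. In M1 6 instead of 10 of these genes rose without M0 replicate 3 or M1 replicate 1, and in M4 5 instead of 3 fell without M4 replicate 2. MMP9 rose by 6.13, 6.72, 6.06, 5.29 and 6.73, and of 13 metalloproteinase and remodelling genes 3 to 7 rose and 2 to 4 fell (4 to 7 and 2 to 4 adjusted over the list alone, camera 0.026 to 0.88, estimated correlation 0.48 to 0.96), with camera calls in M2 and M4.1. In M4 2 instead of 4 of them fell without M0 replicate 4 or M4 replicates 1, 3 or 4, and 5 instead of 3 rose without M4 replicate 1. PLVAP, a gene of vessel walls, rose by 1.52, 1.46, 1.11, 1.29 and 1.24, and of 19 endothelial genes 2 to 6 rose and 1 to 4 fell (2 to 6 and 1 to 4 adjusted over the list alone, camera 0.16 to 0.94, estimated correlation 0.69 to 0.97). The myelin gene MBP changed by -1.3, -2.39, -2.15, -3.23 and -2.19, and of 6 melanocyte, Schwann cell and nerve genes 0 rose and 3 to 4 fell (0 and 3 to 4 adjusted over the list alone, camera 0.014 to 0.19, estimated correlation 0.19 to 0.46), with camera calls in M3 and M4. The stem cell factor receptor gene KIT changed by -1.86, -1.64, -1.89, -2.17 and -1.67, and of 5 dendritic, Langerhans and mast cell genes 0 to 2 rose and 1 fell (0 to 2 and 1 adjusted over the list alone, camera 0.58 to 0.98, estimated correlation 0.87 to 0.99). SPP1 (osteopontin) changed by -5.47, -3.14, -4.4, -5.39 and -2.65, and of 15 macrophage genes 0 to 4 rose and 1 to 2 fell (0 to 4 and 1 adjusted over the list alone, camera 0.35 to 0.88, estimated correlation 0.88 to 0.97). The 4 were in M2, with 2 without M0 replicates 2, 3 or 5 or M2 replicate 4, and 1 without M2 replicate 3. LOX, which crosslinks collagen, fell by 1.81 in M1, and of 24 matrix and fibroblast genes 1 to 9 rose and 4 to 9 fell (1 to 9 and 4 to 9 adjusted over the list alone, camera 0.32 to 0.77, estimated correlation 0.87 to 0.97). In M2 the matrix genes that fell went from 4 to 2 without M0 replicates 1 or 4 or M2 replicate 4, and to 1 without M0 replicate 2 or M2 replicate 2. Those that rose in M3 went from 4 to 2 without M0 replicate 1, 1 without M0 replicates 2, 3 or 4, 7 without M0 replicate 5 and 0 without M3 replicate 1. Those that rose in M4.1 went from 6 to 3 without M0 replicates 2 or 3 or M4.1 replicates 1 or 3, and without M0 replicate 5 4 rose in M1 and 4 in M4. CIDEA, a lipid droplet gene, changed by -6.35, -4.62, -5.15, -5.92 and -4.45, and of 7 adipocyte genes 1 rose and 2 to 4 fell (1 to 2 and 2 to 5 adjusted over the list alone, camera 0.28 to 0.57, estimated correlation 0.49 to 0.74). The complement receptor gene CR2 changed by -3.67 ± 0.69 in M1, and of 5 B cell and plasma cell genes 1 to 2 rose and 1 to 3 fell (1 to 2 and 1 to 3 adjusted over the list alone, camera 0.44 to 0.95, estimated correlation 0.71 to 0.97). Of 6 T cell and NK cell genes 0 to 1 rose and 0 fell (0 and 0 adjusted over the list alone, camera 0.77 to 0.98, estimated correlation 0.96 to 0.99). Outside the joint analysis, CD27 of that list, chosen after its values were seen, was called higher in M1 and M4.1. The changes were 1.84 ± 0.62 (edgeR adjusted p = 0.027) and 2.21 ± 0.77 (edgeR adjusted p = 0.039). CD27 was not called in M2 or M3, and other members of that list outside the joint analysis were not called. Of 13 interferon and type 1 genes 0 to 6 rose and 0 to 1 fell (0 to 6 and 0 adjusted over the list alone, camera 0.35 to 0.86, estimated correlation 0.82 to 0.99). The 6 were in M4, where 1 rose without M4 replicate 3. ND3, a mitochondrial complex I gene, changed by -0.97 ± 0.14 in M2, and of 13 mitochondrially encoded genes 1 rose and 3 to 9 fell (1 and 3 to 9 adjusted over the list alone, camera 0.033 to 0.54, estimated correlation 0.59 to 0.96), with a camera call in M2 alone. In M4 6 instead of 3 of these fell without M0 replicate 1 or M4 replicate 1. The median and the camera test differed in sign for matrix and B cell genes in M1, T cell genes in M3 and M4, dendritic cell genes in M4.1, and barrier lipid genes in M1, M2 and M4.1.

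**Figure D3:**
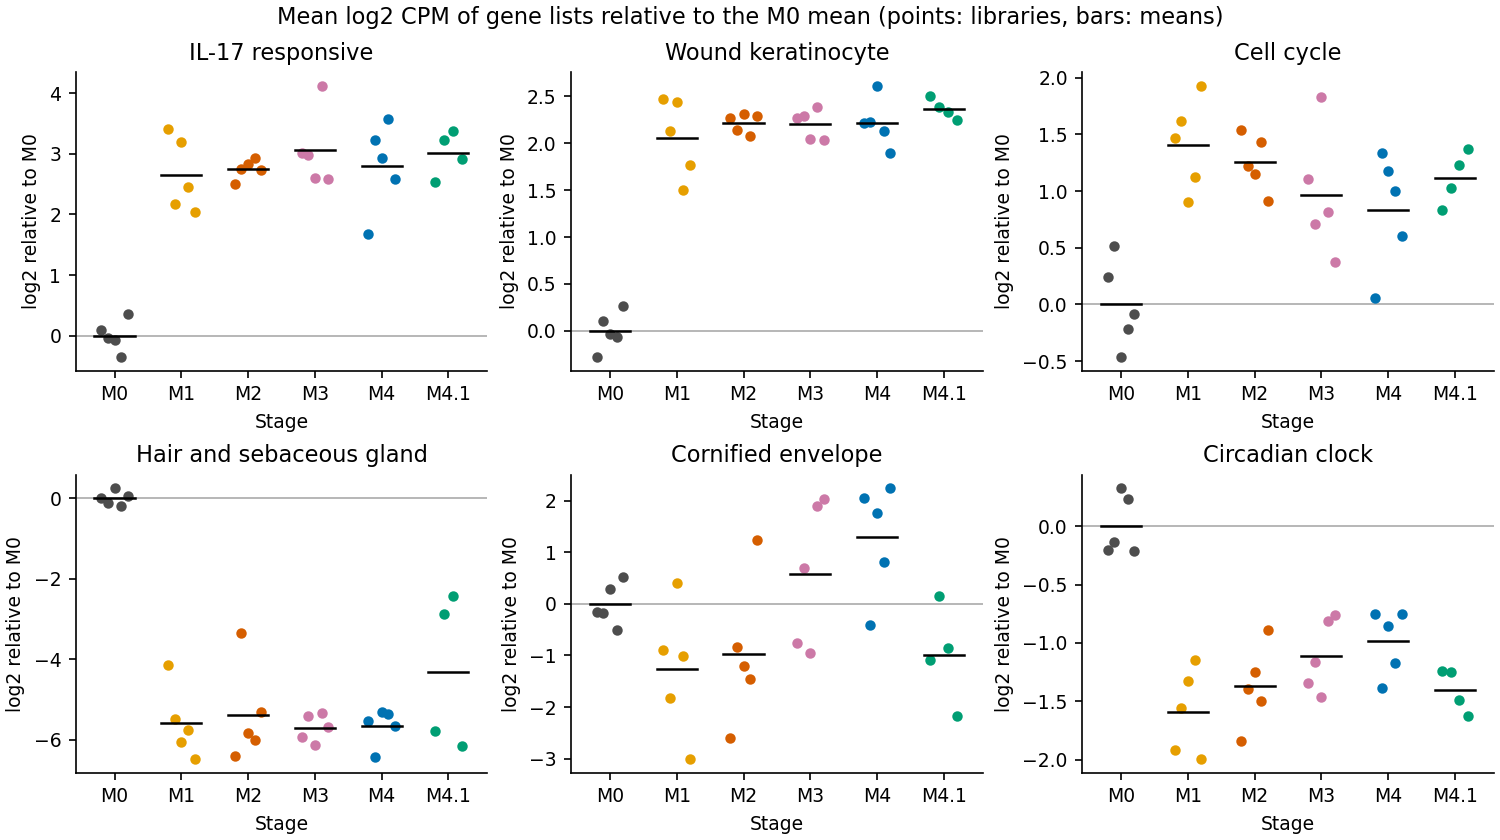
Mean log2 CPM of 6 gene lists per library relative to the M0 mean (y axis) by stage (x axis), with 1 point per library and a bar at the mean. Wound genes are higher and hair follicle and sebaceous gland genes lower in all 24 lesion libraries than in M0, and the hair list is nearest to M0 in 2 of the 4 M4.1 libraries.

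The study's title concerns an inflammatory pathway driven by IL-17F, and cytokines of the IL-17 list were therefore read in every stage. IL17F (ENSBTAG00000016835) encodes a cytokine that makes keratinocytes release neutrophil-attracting chemokines. It is listed in the deposited tables of M1, M3 and M4.1 only, so it was tested within these tables with edgeR. Its level was 4.08 ± 3.13 CPM in M1 (n = 5) and 0.391 ± 0.559 in M0 (n = 5), a log2 change of 3.2 ± 0.84 (adjusted p = 0.0072). In M3 it was 2.47 ± 0.970 CPM against 0.382 ± 0.546 (n = 5 and 5), a log2 change of 2.59 ± 0.72 (adjusted p = 0.012). In M4.1 it was 3.56 ± 3.1 CPM against 0.415 ± 0.592 (n = 4 and 5), a log2 change of 3.01 ± 0.85 (adjusted p = 0.013). These levels rest on 70, 43 and 64 counts in all, against 11 in M0, of which 8 lie in M0 replicate 1. Without that library the changes were 4.5 in M1, 3.87 in M3 and 4.34 in M4.1. The tables of M2 and M4 do not list IL17F, so its level in these stages was not analysed, and IL17A is in no table. If the limit of 1 CPM alone left IL17F out, fewer than 5 libraries of M2 and M0 together exceeded it, and likewise for M4. The tests of IL17F therefore cover only stages in which it passed that limit. Without M4.1 replicate 3, which held 38 of the 64 counts, the change in M4.1 was 2.29 (adjusted p = 0.062).

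Some other genes of the list outside the joint analysis also rose. Each is given for the stages whose tables list it, and the other tables leave it out. Genes with few or no counts in M0 enter a table largely through the stage's own libraries, which favours a rise there. IL6, a fever-inducing cytokine with 3 counts in M0, had ratios (95% counting interval) of 726 (248 to 3523) in M1, 480.1 (164 to 2331) in M2 and 716 (244 to 3475) in M4.1. CXCL5, a further neutrophil chemokine, rose by 7.34 ± 0.68, 7.31 ± 1.08 and 7.70 ± 0.88 in the same stages. CSF3, which drives neutrophil production, rose by 3.60 ± 0.79, 2.91 ± 0.85 and 3.87 ± 0.66. IL36A had no counts in M0 and was at least 37.5-fold higher in M1, 65.9-fold in M3 and 81.1-fold in M4. The receptor subunit gene IL17RC changed by -0.29 ± 0.66 (adjusted p = 0.76) in M1, -0.31 ± 0.46 (adjusted p = 0.62) in M2 and -0.49 ± 0.65 (adjusted p = 0.60) in M3.

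Within the joint analysis, CXCL2 rose by 7.66 ± 1.18, 8.36 ± 1.2, 8.01 ± 1.19, 7.23 ± 1.17 and 8.89 ± 1.23, GRO1 by 7.34 ± 1.08, 7.70 ± 1.09, 7.22 ± 1.08, 6.85 ± 1.07 and 8.30 ± 1.12 and CXCL8 by 8.57 ± 1.28, 8.58 ± 1.28, 8.22 ± 1.27, 6.53 ± 1.25 and 9.01 ± 1.3 in M1, M2, M3, M4 and M4.1. CXCL3 rose by 2.79 ± 0.58, 2.75 ± 0.58, 2.58 ± 0.57, 2.06 ± 0.57 and 3.24 ± 0.60 and CCL20 by 3.55 ± 0.96, 2.76 ± 0.94, 4.98 ± 1.01, 3.57 ± 0.96 and 2.97 ± 0.97, the latter by 2.47 in M3 without M3 replicate 4. The receptor gene IL17RA changed by 0.02 ± 0.11, -0.01 ± 0.11, 0.01 ± 0.11, -0.0023 ± 0.11 and 0.13 ± 0.12, with adjusted p between 0.38 and 0.99. These estimates near 0 changed sign without M0 replicates 1, 2, 3 or 5, M1 replicate 3, M2 replicates 2 or 3, M3 replicates 2, 3 or 5, and M4 replicates 1 or 2, and then lay between -0.07 and 0.07.

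IL36G, an alarm cytokine of the epidermis, rose by 2.60 ± 0.98, 2.4 ± 0.98, 3.99 ± 1.01 and 4.36 ± 1.02 in M1, M2, M3 and M4, and stood at 2.24 ± 1.01 in M4.1 (adjusted p = 0.080). Its antagonist IL36RN rose by 1.93 ± 0.69 in M4 and stood at 0.14 ± 0.67, 0.03 ± 0.67, 1.52 ± 0.68 and -0.38 ± 0.71 in M1, M2, M3 and M4.1. IL23A, a subunit of the cytokine that sustains IL-17 producing cells, rose by 1.63 ± 0.62 in M2 and stood at 1.18 ± 0.64, 1.3 ± 0.65, 1.56 ± 0.64 and 1.47 ± 0.66 in M1, M3, M4 and M4.1. IL36G lost its call in M1 without any of M0 replicates 1 to 4, M1 replicate 1 or M1 replicate 3 (2.13 to 2.51), and in M2 without any of M0 replicates 1 to 4, M2 replicate 4 or M2 replicate 5 (1.14 to 2.4). Without M0 replicate 5 it was 3.66 in M2 and 3.49 with a call in M4.1. IL36RN lost its call in M4 without M0 replicate 2, M0 replicate 4 or M4 replicate 3 (1.76 to 1.84) and gained one in M3 without M3 replicate 1 (1.78). Its small estimates changed sign to -0.56 without M1 replicate 3 in M1, and in M2 to -0.05 without M0 replicate 2, -0.07 without M0 replicate 4, -0.10 without M2 replicate 4 and -0.63 without M2 replicate 5. IL23A lost its call in M2 without M0 replicate 1, M0 replicate 3, M2 replicate 2 or M2 replicate 3 (1.23 to 1.43) and gained one in M4 without M0 replicate 5, M4 replicate 1, M4 replicate 3 or M4 replicate 5 (1.70 to 1.84).

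Comparing M2 with M1 asks what separates acute from early lesions. No single gene of the joint analysis passed the threshold between them. Genes outside the joint analysis, IL17F among them, were not tested between any stages. PTGS2, which makes prostaglandins, differed by 0.87 ± 0.72 on the log2 scale (adjusted p = 1.0) and S100A7 by 2.68 ± 1.42 (adjusted p = 1.0), which became -0.08 without M2 replicate 5. With edgeR 0 genes passed adjusted p = 0.05 and 417 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Matrix and fibroblast genes ranked higher in M2 (camera adjusted p = 6.8e-10, adjusted p = 0.64 with an estimated correlation), as did macrophage genes (camera adjusted p = 0.0088, adjusted p = 0.64 with an estimated correlation). Mitochondrially encoded genes ranked lower (camera adjusted p = 1.6e-06, adjusted p = 0.64 with an estimated correlation), as did cell cycle genes (camera adjusted p = 0.0099, adjusted p = 0.64 with an estimated correlation). No member of these 4 lists passed the threshold over all genes tested, 1 macrophage gene passed it higher when adjusted over the list alone, and the rotation test fry called 0 of 25 lists. Camera called 4 lists with all libraries, 7 without M1 replicate 1 or M2 replicate 1, and 2 without M2 replicate 3.

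Comparing M3 with M2 asks what separates healing from acute lesions. No single gene of the joint analysis passed the threshold. CCL20 differed by 2.22 ± 0.88 (adjusted p = 0.52), or -0.29 without M3 replicate 4, and LAP, a defensin, by 2.04 ± 0.87 (adjusted p = 0.52). With edgeR 0 genes passed, 923 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Camera ranked cornified envelope genes higher (camera adjusted p = 8.8e-10, adjusted p = 0.68 with an estimated correlation), and barrier lipid genes (camera adjusted p = 0.0051, adjusted p = 0.68 with an estimated correlation). Matrix genes ranked lower (camera adjusted p = 8.1e-06, adjusted p = 0.68 with an estimated correlation), as did metalloproteinase genes (camera adjusted p = 0.014, adjusted p = 0.68 with an estimated correlation). Camera called 9 lists in all and fry 0. Camera called 4 lists without M2 replicate 3, M3 replicate 3 or M3 replicate 5, and 3 without M3 replicate 2.

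Comparing M4 with M3 asks what separates chronic from healing lesions. CCL20 differed by -1.41 ± 0.85 (adjusted p = 0.79), or 1.1 without M3 replicate 4, and the neutrophil chemokine CXCL8 by -1.69 ± 0.83 (adjusted p = 0.72). With edgeR 0 genes of the joint analysis passed and 715 had an unadjusted p under 0.05. DESeq2 called 2 genes, ELOVL3 at -6.55 and SDR16C6 at -5.99, which were named after their values were seen, and limma-voom 0. Metalloproteinase genes ranked lower in M4 (camera adjusted p = 0.0011, adjusted p = 0.74 with an estimated correlation) and cornified envelope genes higher (camera adjusted p = 0.0038, adjusted p = 0.78 with an estimated correlation). Camera called 4 lists in all and fry 0. Camera called 0 lists without M3 replicate 1, 7 without M3 replicate 5 and 9 without M4 replicate 4.

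**Figure D4:**
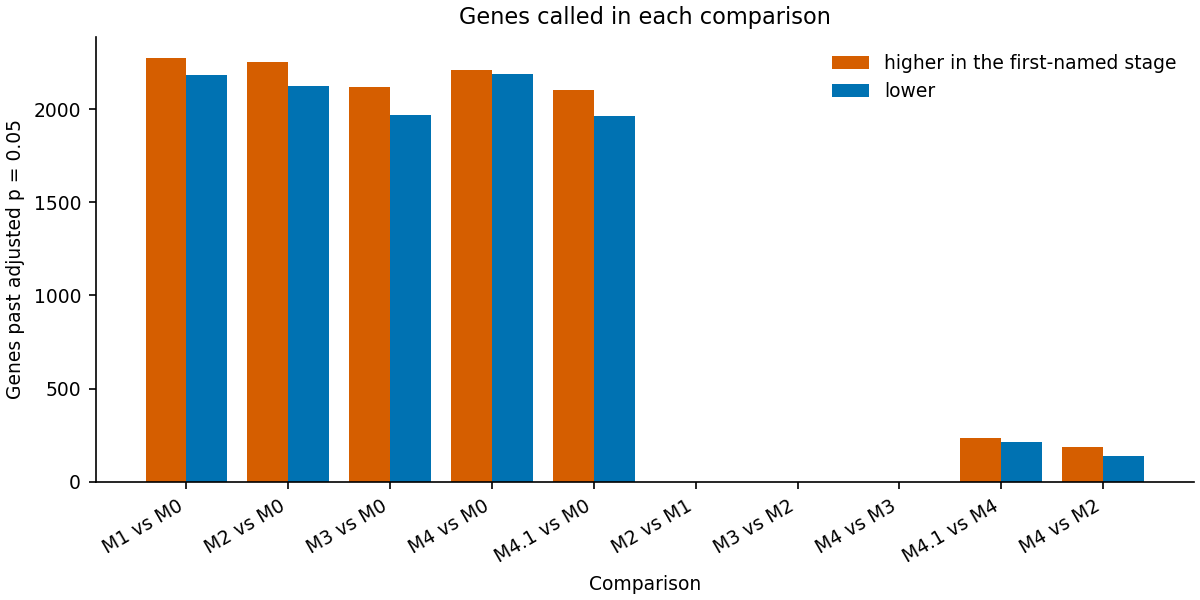
Number of genes past adjusted p = 0.05 (y axis, starting at 0) in each of the 10 comparisons (x axis), split into higher and lower genes. Within the joint analysis each stage differs from M0 by 4064 to 4459 genes, and the comparisons between stages have 446, 323 or 0 genes.

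Comparing M4.1 with M4 asks what separates a chronic lesion with renewed activity from one without. Among the genes past the threshold, single late keratinocyte genes were lower and single hair genes higher in M4.1. KRT2, a keratin of the upper epidermis, was at 0.80 ± 0.963 CPM in M4.1 (n = 4) and 92.4 ± 103 in M4 (n = 5), a log2 change of -6.87 ± 1.81 (edgeR adjusted p = 0.035). KRT78, a further epidermal keratin, changed by -6.78 ± 1.77, the protease inhibitors SPINK7 and SERPINA12 by -6.81 ± 2.01 and -6.60 ± 1.68, and KLK14, a protease of skin shedding, by -5.57 ± 1.54. KRT25 rose by 7.55 ± 1.87 and ELOVL3 by 6.58 ± 1.77. The hair keratin KRT35 was at least 68.2-fold and KRTAP4-7 at least 64.6-fold higher, and KRT31 had a ratio of 202 (95% counting interval 55.5 to 1672). JCHAIN, which joins secreted antibodies of plasma cells, rose by 2.54 ± 0.58, or by 1.25 without a call when M4.1 replicate 4 was left out.

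In M4.1 against M4, 446 of 10371 genes passed adjusted p = 0.05, 233 higher and 213 lower. Of 25 cornified envelope genes, 0 rose and 3 fell over all genes tested (0 and 21 adjusted over the list alone, camera adjusted p = 1.3e-09, adjusted p = 0.36 with an estimated correlation). Of 13 metalloproteinase and remodelling genes, 2 rose and 0 fell over all genes tested (10 and 0 adjusted over the list alone, camera adjusted p = 1.0e-05, adjusted p = 0.36 with an estimated correlation). Of 23 hair follicle and sebaceous gland genes, 9 rose and 1 fell over all genes tested (14 and 1 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.55 with an estimated correlation). This rise lies in 2 of the 4 M4.1 libraries: the mean log2 CPM of the hair list relative to M0 was -2.86 and -2.43 in M4.1 replicates 2 and 3 and -5.78 and -6.15 in M4.1 replicates 1 and 4, against -6.41 to -5.31 in M4. The 9 became 0 without M4 replicate 1, M4 replicate 5 or M4.1 replicate 3, 1 without M4 replicate 3 and 5 without M4 replicate 4. Cornified envelope genes that fell went from 3 to 8 without M4 replicate 2 and to 5 without M4.1 replicate 2. Camera called 13 lists and fry 3. The number of genes depended on single libraries: it was 0 without M4 replicate 1 or M4.1 replicate 3, 5 without M4 replicate 5, 33 without M4.1 replicate 4, 82 without M4 replicate 3, 216 without M4.1 replicate 1 and 847 without M4 replicate 2. Those 5 genes were RAB27A, RASA3, RAB32, RSU1 and TINAGL1, chosen after their values were seen. Estimates without a library were often close to those with all libraries, with KRT2 at -6.47 without M4 replicate 1 and -6.40 without M4.1 replicate 3, and KRT25 at 7.33 and 6.79, while KLK14 went from -5.57 to -7.89 without M4.1 replicate 3. All 11 named genes lost their calls without M4 replicate 1 (adjusted p = 0.079 to 0.096), M4 replicate 5 (adjusted p = 0.054 to 0.12) or M4.1 replicate 3 (adjusted p = 0.072 to 0.15). Without M4 replicate 3 the calls of all but KRT35 ended (0.059 to 0.079). Without M4.1 replicate 4 the calls of ELOVL3, JCHAIN, KLK14, KRT2, KRT78, SERPINA12 and SPINK7 ended (0.065 to 0.18). Without M4.1 replicate 1 the calls of KLK14, KRT2, KRT78, SERPINA12 and SPINK7 ended (0.061 to 0.093). Without M4.1 replicate 2 the calls of KLK14 and SPINK7 ended (0.060 to 0.065). Without M4 replicate 4 the calls of ELOVL3 ended (0.057). JCHAIN then stood at 1.25 without M4.1 replicate 4. Under DESeq2 963 genes were called, under limma-voom 168, and 8 without the 2 libraries with the lowest TMM factors.

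Comparing M4 with M2 asks what separates chronic from acute lesions. ISG15, an interferon-induced gene, was at 53.7 ± 104 CPM in M4 and 2.17 ± 1.08 in M2 (n = 5 and 5), a log2 change of 4.64 ± 1.22 (edgeR adjusted p = 0.040), or 1.80 without M4 replicate 3. VSIG8, a gene of hair and upper epidermis, rose by 3.32 ± 0.89, TCN1 by 2.67 ± 0.74, the ubiquitin ligase gene MARCHF3 by 2.71 ± 0.60 and the galectin-like gene LGALSL by 2.35 ± 0.51. COMP, a cartilage and scar matrix gene, changed by -4.31 ± 0.89, and SFRP4, an inhibitor of WNT signals, by -3.55 ± 0.84. CCN3 changed by -2.59 ± 0.49, ELOVL3 by -6.64 ± 1.74 and MOGAT2, an enzyme of fat synthesis, by -5.93 ± 1.60.

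In M4 against M2, 323 genes passed adjusted p = 0.05, 186 higher and 137 lower. Of 25 cornified envelope genes, 1 rose and 0 fell over all genes tested (18 and 0 adjusted over the list alone, camera adjusted p = 4.1e-11, adjusted p = 0.41 with an estimated correlation). Of 13 metalloproteinase and remodelling genes, 0 rose and 1 fell over all genes tested (0 and 9 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.41 with an estimated correlation). Of 24 matrix and fibroblast genes, 0 rose and 1 fell over all genes tested (0 and 3 adjusted over the list alone, camera adjusted p = 2.7e-06, adjusted p = 0.41 with an estimated correlation). Without M2 replicate 5, 15 cornified envelope genes rose, and without M4 replicate 2, 6 did. Camera called 10 lists and fry 7. The number of genes was 0 without M2 replicate 3 or M4 replicate 1, 16 without M2 replicate 2, 19 without M4 replicate 5, 21 without M4 replicate 3, 32 without M2 replicate 1, 35 without M2 replicate 4, 785 without M4 replicate 2 and 900 without M2 replicate 5. Without M2 replicate 3 and without M4 replicate 1, CCN3 was at -2.68 and -2.51, LGALSL at 2.23 and 2.28, VSIG8 at 3.07 and 3.03 and SFRP4 at -2.49 and -3.31. All 10 named genes lost their calls without M2 replicate 3 (adjusted p = 0.055 to 0.11) or M4 replicate 1 (adjusted p = 0.070 to 0.11). Without M4 replicate 3 the calls of all but CCN3 ended (0.060 to 0.32). Without M4 replicate 5 the calls of all but CCN3 ended (0.055 to 0.085). Without M2 replicate 2 the calls of all but CCN3 and COMP ended (0.054 to 0.10). Without M2 replicate 4 the calls of all but CCN3 and COMP ended (0.061 to 0.085). Without M2 replicate 1 the calls of all but CCN3, COMP and SFRP4 ended (0.061 to 0.10). Without M4 replicate 4 the calls of ELOVL3, MOGAT2 and TCN1 ended (0.057 to 0.059). ISG15 then stood at 1.80 without M4 replicate 3. Under DESeq2 883 genes were called and under limma-voom 315. With a replicate block 62 were called, and 0 against a fold change of 1.5 or without the 2 libraries with the lowest TMM factors.

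**Figure D5:**
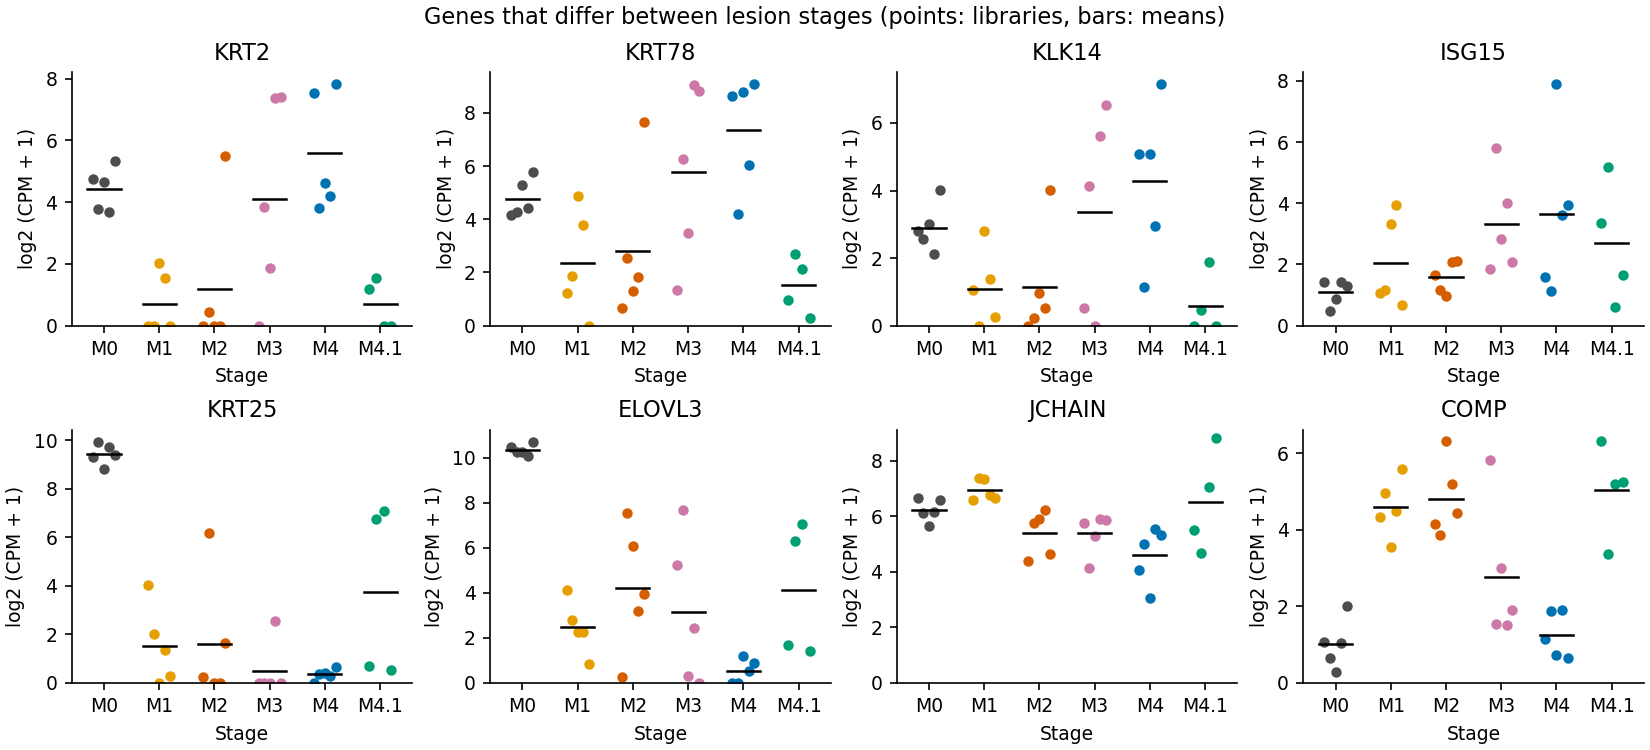
Level of 8 genes per library (y axis, log2 of CPM + 1) by stage (x axis), with 1 point per library and a bar at the mean. KRT2, KRT78 and KLK14 are lower on average and KRT25, ELOVL3, JCHAIN and COMP higher in M4.1 than in M4, and ISG15 is high in single libraries.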

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

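All tests of explanations and all counts of other splits in this part were chosen after the results were seen.

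In single groups, 24 sets of levels and totals were tested for a library far from the others. Such a library was found for 4 items, where IL17F in M0 is 1 item although it was tested in each of 3 tables. No chance rate is given, since the levels are CPM with some at 0. PI3 stood at 2.505 CPM in M0 replicate 5 and at 0 in the other M0 libraries. KRT6B stood at 145900 CPM in M4 replicate 1, where the next library had 74890. IL17F in M0 replicate 1 was at 1.35 CPM in the table of M1, 1.32 in that of M3 and 1.43 in that of M4.1. ISG15 stood at 239 CPM in M4 replicate 3, where the next library had 14.4. No explanation of these libraries was tested.

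Genes outside the joint analysis also differed from M0 within single tables. Of 684, 676, 585, 462 and 932 such genes in the tables of M1, M2, M3, M4 and M4.1, edgeR called 144, 164, 113, 114 and 236.

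Between stages, tests of the difference itself called 446 genes for M4.1 against M4 and 323 for M4 against M2. Camera called 4 lists for M2 against M1, 9 for M3 against M2, 4 for M4 against M3, 13 for M4.1 against M4 and 10 for M4 against M2. With an estimated correlation it called 0 lists in each of these. In M4.1 against M4 the log2 changes were -6.87 for KRT2, -6.78 for KRT78, -6.81 for SPINK7, -6.60 for SERPINA12, -5.57 for KLK14, 7.55 for KRT25, 6.58 for ELOVL3 and 2.54 for JCHAIN. KRT35 was at least 68.2-fold and KRTAP4-7 at least 64.6-fold higher, and KRT31 had a ratio of 202. In M4 against M2 they were 4.64 for ISG15, 3.32 for VSIG8, 2.67 for TCN1, 2.71 for MARCHF3, 2.35 for LGALSL, -4.31 for COMP, -3.55 for SFRP4, -2.59 for CCN3, -6.64 for ELOVL3 and -5.93 for MOGAT2. Without M4 replicate 3 ISG15 was at 1.80, and without M4.1 replicate 4 JCHAIN was at 1.25, both without a call. The Results give the libraries without which the named genes lose their calls. The part on processing gives the libraries and settings under which the counts of genes and lists change.

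Other splits of the libraries were counted with fits of the 2 groups alone, drawing 60 of 126 splits. For M1, M2, M3, M4 and M4.1 against M0 the real split gave 4325, 4472, 3584, 4151 and 4485 genes, the highest other split 1, 0, 31, 0 and 999, and 1 split of 60, the real one, gave as many in each. For M4.1 against M4 the real split gave 428 genes and the highest other 4, and again 1 of 60 gave as many. For M4 against M2 the real split gave 255 genes, and 2 of 60 gave as many. A share of 1 of 60 is the smallest that 60 draws can give. For the counts against M0 the highest other split stayed far below the real one, which argues against a chance split. The count for M4.1 against M4 is 0 without M4 replicate 1 or M4.1 replicate 3, so the splits do not settle chance there. For M4 against M2 the share of splits is under 0.05, but the other split gave 1041 genes, several times the real count. It was the only other drawn split with a called gene, and what lies behind its count was not tested. The count is 0 without M2 replicate 3 or M4 replicate 1, where CCN3 stood at -2.68 and -2.51, LGALSL at 2.23 and 2.28, COMP at -3.71 and -4.24 and SFRP4 at -2.49 and -3.31, and adjusted p of the 10 named genes lies between 0.055 and 0.11. For M2 against M1, M3 against M2 and M4 against M3, genes at an unadjusted p under 0.05 numbered 298, 643 and 359. Of 60 splits 47, 12 and 21 gave as many, with highest others of 1000, 1601 and 1389, so chance cannot be excluded there. What lies behind the high counts of single splits was not tested.

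Between 4064 and 4459 genes differed between each stage and M0. The M0 samples came from a slaughterhouse, as did 2 unnamed M1 samples, so source was tested on a scale from M0 (0) to the mean of the other stages (1). The second-lowest M1 library lay at 1.02 and the lowest at 0.932, while M0 libraries lay between -0.0484 and 0.0390. This argues against source as the whole cause. Body site cannot be told apart from disease, since 0 lesion libraries carry the site label of the controls.

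Genes of hair follicles, sebaceous glands and sweat glands were lower in all 5 stages. Scaling would move all genes alike, but the median log2 change of the 34 genes lay at least 3.75 under that of all genes in each stage (highest difference -3.75), which argues against it. Source as the whole cause is argued against as well, with the second-lowest M1 library at 1.03 on the scale above. A smaller share of hair and glands in the biopsy, by body site or by disease, remains open, since 0 lesion libraries carry the site label of the controls. In M4.1, 2 libraries lay at 0.476 and 0.571 and the highest at 1.17.

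Most circadian clock genes were lower in all 5 stages. A shift in the time of day of sampling would move ARNTL opposite to PER1, DBP and NR1D1, but ARNTL was called in their direction in 5 of 5 stages. This argues against a shift of the cycle as the whole cause. The second-lowest M1 library lay at 1.1 on the scale, which argues against source as the whole cause. Body site and disease stay open, as does a weaker cycle or a different mix of cells, which were not tested.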

How the results depend on the processing

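The robust fit, the authors' layout of 1 table at a time, leaving out the 2 libraries with a TMM factor under 0.8 and the refits within single tables were chosen after the data were seen, and the other alternatives before. The numbers of genes called in each stage against M0 stayed within 1.5 times under RLE size factors, no filter, at least 10 counts in at least 10 libraries, a replicate block, only the 2 groups, limma-voom, DESeq2, the robust fit, the authors' layout and without the 2 libraries. A test against a fold change of 1.5, stricter by construction, called 1991, 1932, 1653, 1973 and 1786 genes in M1, M2, M3, M4 and M4.1. Leaving out 1 library gave 4043 to 4505, 3896 to 4276, 3625 to 3939, 3948 to 4194 and 3446 to 3810. The authors' deposited tables call 4516, 4685, 3773, 4363 and 4656 genes, of which 4142, 4160, 3544, 4031 and 3897 are also called in the joint analysis.

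Between stages the counts depended on the settings, and the cause was not tested. M4.1 against M4 gave 46 genes with a replicate block, 168 with limma-voom, 963 with DESeq2, 8 without the 2 libraries and 0 against a fold change of 1.5, and 0 to 847 with 1 library left out. M4 against M2 gave 62 with a replicate block, 883 with DESeq2, 0 without the 2 libraries and 0 against a fold change of 1.5, and 0 to 900 with 1 library left out. The edgeR count for M4.1 against M4 was 0 without M4 replicate 1 or M4.1 replicate 3, and for M4 against M2 without M2 replicate 3 or M4 replicate 1. M4 replicate 1 has the lowest TMM factor, 0.631. M4 against M3 gave 2 genes with DESeq2 and 0 with limma-voom. The edgeR counts for M2 against M1, M3 against M2 and M4 against M3 were 0 with each library left out, with 417, 923 and 715 genes at an unadjusted p under 0.05 with all libraries.

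With an estimated correlation the lists called in M1, M2, M3, M4 and M4.1 against M0 went from 11, 13, 13, 13 and 12 to 2, 2, 1, 1 and 2. Between stages they went to 0 in M2 against M1, 0 in M3 against M2, 0 in M4 against M3, 0 in M4.1 against M4 and 0 in M4 against M2. The test fry called 0 lists in M2 against M1, 0 in M3 against M2, 0 in M4 against M3 and 3 in M4.1 against M4. With 1 library left out, camera called 8 to 14 lists in M2 against M0, 2 to 7 in M2 against M1, 3 to 10 in M3 against M2 and 0 to 9 in M4 against M3. The low ends were reached without M2 replicate 3, M2 replicate 3, M3 replicate 2 and M3 replicate 1.

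Leaving aside CD27, the text names 95 genes in 303 pairs of gene and comparison, 280 of them called. Of 5948 fits under an alternative, 5617 kept direction and side of the threshold, 274 lost the call, 16 gained one and 41 changed sign. With 1 library left out, 122 of 259 fits between stages and 25 of 2708 against M0 lost the call. The sign changes concern uncalled values near 0 or resting on 1 library. IL17RA in M1 was -0.0036 with RLE, -0.011 with 10 counts in 10 libraries and -0.0071 with DESeq2. IL17RA in M3 was -0.015, -0.026 and -0.020 under these, -0.033 without the 2 libraries and -0.0015 with only the 2 groups. IL17RA in M4 was 0.0021 without a filter, 0.067 without the 2 libraries and 0.0055 with limma-voom. IL36RN was -0.72 with limma-voom in M1. In M2 it was -0.0033 with RLE, -9.9e-06 with 10 counts in 10 libraries, -0.20 with a replicate block, -0.61 with limma-voom and -0.00038 with DESeq2. With 1 library left out IL17RA ran from -0.058 to 0.051 in M1, -0.090 to 0.017 in M2, -0.074 to 0.040 in M3 and -0.085 to 0.073 in M4, and IL36RN from -0.56 to 0.45 in M1 and -0.63 to 0.28 in M2. S100A7 in M2 against M1 ran from -0.076 (without M2 replicate 5) to 3.60, and CCL20 from -0.29 to 2.53 in M3 against M2 and -1.94 to 1.1 in M4 against M3, both extremes with a changed sign being without M3 replicate 4.

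The gene tests use counts, so no pseudocount and no filter on normalized values was tried for them. The prior count of 2 for principal components and list scores was not varied. The filter on low counts was varied. M1 against M0 gave 4532 genes without a filter and 4140 with at least 10 counts in at least 10 libraries, against 4459 with filterByExpr. No label says whether replicate numbers pair libraries, and the replicate block was treated as an arbitrary grouping. Residuals of 70 pairs with 1 number correlated with a median r of -0.0129 (-0.359 to 0.414), and 17 pairs exceeded 0.1. The median r of pairs with different numbers was -0.0048. Of 29 libraries, 7 correlated best with a library of their own number. A median near 0 cannot exclude that single pairs share an animal or farm. Depth limits genes with few counts, and IL17F rests on 43 to 70 counts per stage.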

Other observations

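Genes in single tables outside the joint analysis were read after their values were seen, with the edgeR fit within each table. Each is given for every stage whose table lists it, and its level in the other stages was not analysed. With few counts in M0, such genes enter a table largely through the stage's own libraries over 1 CPM. This favours a rise in the listed stages in advance. MMP1, which degrades collagen, rose by 6.26 ± 1.13 in M1, 5.58 ± 1.03 in M2, 4.97 ± 0.89 in M3 and 6.53 ± 0.84 in M4.1 on the log2 scale. The neutrophil receptor gene CXCR1 rose by 3.96 ± 0.79 in M1 and 4.51 ± 0.52 in M4.1. CSF3R, the receptor gene for the neutrophil growth factor CSF3, rose by 3.44 ± 0.61 in M1, 2.69 ± 0.66 in M2, 2.76 ± 0.69 in M3 and 3.67 ± 0.54 in M4.1. MZB1, a gene of antibody-secreting cells, rose by 3.53 ± 0.59 in M1, 2.61 ± 0.51 in M3 and 3.72 ± 1.02 in M4.1, or 2.06 in M4.1 without M4.1 replicate 4. The water channel gene AQP5, a member of the sweat gland list, had 2 counts in M0. Its ratio was 159 (95% counting interval 43.5 to 1326) in M3 and 504 (139 to 4171) in M4. Differences between these stages were not tested for these genes.

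No pair of libraries of a group holds copies of 1 library by its counts: the smallest chi-square per degree of freedom between any pair of libraries of a group was 10.9, where copies of 1 library would give about 1.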
